A study of Mus musculus with 4 samples.

How the data were processed

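RNA was sequenced from fetal liver cells of mice, transduced with a retrovirus carrying the MLL-AF9 fusion oncogene and sorted by the vector's GFP marker, per the series' design text. The 4 libraries fall into 2 genotypes by their labels, with 2 wild type and 2 Prl2 knockout libraries. Prl2 is the older name of Ptp4a2, which encodes the phosphatase PRL2. Replicate numbers were taken from the titles, and the table's columns were matched to samples by the short names in the sample descriptions. The labels do not say whether replicates came from separate embryos, litters or cultures, so p-values measure only the spread between these libraries. In the wild type libraries Xist had 11147 and 9 counts and Ddx3y 12 and 1271, which argues against technical replicates there. In the knockout the spread may be technical.

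The authors deposited 1 table with whole-number read counts per gene and library. Per the submitters' processing notes, STAR, Bowtie2, featureCounts and the mm10 mouse genome were used. Their versions, their roles and the strand setting of the counting are not given in the sources used here. Per the file headers, the authors' table also holds a log2 fold change, a p-value and an adjusted p-value for the knockout against the wild type. Per the file headers, the deposited table also gives a length in bp for each gene. It is not the genomic span: for Ptp4a2 it is 4377 bp, while the gene runs from 129811219 to 129850003. Gene length below means this deposited length. The table lists 13614 genes, each with a CPM (the count scaled to the library total) above 0.5 in at least 2 libraries, and the smallest total of a gene over the 4 libraries is 23 counts. It was therefore filtered before deposit, and genes under that level were not analysed here. The smallest adjusted p-value of the authors' deposited table is 13614 times its smallest p-value, which equals the number of genes listed. Of the gene IDs, 13611 were found in the GENCODE M21 annotation, and 99.6% of the genes had the same chromosome, start and end there. Symbols of 18 genes had been turned into dates by a spreadsheet and were restored from their IDs. By type, 11386 genes are protein-coding, 1218 are pseudogenes and 781 are lncRNA genes.

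Library totals in the table lie between 14625725 and 15422309 counts, and the 10 most abundant genes hold 3.26% to 3.90% of them. Intervals and lower bounds for genes at 0 counts cover counting error only. The bound for a gene at 0 uses 3 counts per library. The 2 libraries of each genotype differed by more than sampling noise, with a chi-square per gene of 34.4 in the wild type and 19.1 in the knockout, so they were treated as 2 samples each.

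Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust estimation on the deposited counts. TMM factors scaled the libraries, filterByExpr kept all 13614 genes, and p-values were two-sided and adjusted by the Benjamini-Hochberg method. Genes at an adjusted p of 0.05 or less were called. CPM values are scaled by the TMM factors. The standard error of a log2 fold change is the fitted coefficient divided by the root of the F statistic, and intervals are at 95%. Genotype was the single term of the model.

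Before the data were examined, 37 gene lists were fixed, including markers of cell types that a sorted fetal liver population could hold. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. The main test used the preset inter-gene correlation of 0.01, and the correlation estimated from the residuals was an alternative. With so few libraries that alternative has little power, so a list that fails it is not shown to be unchanged. The adjustment runs over all 37 lists. Calls of members were counted after adjustment over all genes and again adjusted over the list alone. The rotation test fry gives a p-value for a shift of the list's genes, on balance, in 1 direction and a mixed p-value for change in either direction. It does not compare the list with other genes.

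The rule for named genes was also fixed before the data were examined. It takes Ptp4a2, Ptp4a1, Ptp4a3, Trp53, Mdm2, Cdkn1a, Bax, Bbc3 and Pmaip1 in any case. It adds up to 8 called genes per direction with the largest log2 fold change among those with a mean log2 CPM of 3 or more and no overlap of the groups. Of each list it adds up to 4 called members, or up to 2 of the most abundant members where none was called. For most lists without a call 1 member was taken, and for 8 lists none, to keep the number of named genes low. That reduction was made after the values were seen. The quasi-likelihood test left 1 gene for the part of the rule on size, so the same rule was also applied to the calls of the authors' deposited table, a choice made after the data were seen. Any other gene is said to have been chosen after its values were seen. Some genes that the rule takes are not reported here.

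Alternatives were DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, other scaling factors, other filters, a fit without robust estimation, replicate number as a block and leaving out each library in turn. After the data were seen, a crossed pairing of the replicate numbers, removal of each library's trend on gene length (loess, span 0.3), edgeR's earlier quasi-likelihood method and leaving out genes on X and Y were added. A fit with edgeR's likelihood ratio test gave p-values within 5.51e-10 of those in the authors' deposited table for all genes.

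The scripts were tested on simulated counts with the means and library sizes of these data. Genes were drawn independently of each other. The spread of each gene came from the distribution found by the quasi-likelihood fit, so the simulation favours that test and cannot rank the tools. In it, 50 genes were changed at each of 4 fold sizes. Of these 50, the quasi-likelihood test over 13312 genes called 1 at 1.5-fold, 4 at 2-fold, 26 at 4-fold and 32 at 8-fold, with 3 unchanged genes called. The likelihood ratio test called 5, 28, 43 and 47 of them, with 66 unchanged genes called. DESeq2 over 13614 genes called 7, 28, 43 and 45, with 61 unchanged genes called. A simulated list of 26 genes raised by 0.35 on the log2 scale had a camera p of 4.3e-07 with the preset correlation and 0.0299 with an estimated correlation. Of 200 random lists, 3 and 0 had a p under 0.05. As the simulated genes were independent, this cannot show how often the preset correlation calls real lists whose members move together.

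Retrocopies, processed pseudogenes made by reverse transcription of another gene's RNA, were matched with blastn 2.17.0 to protein-coding transcripts of GENCODE M21. A match needed 80% identity over at least 50% of the retrocopy, and 1086 of the 1114 retrocopies in the table had one. GC content was taken from each gene's longest transcript.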

Results

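The data are RNA-seq read counts per gene in mouse fetal liver cells that carry the MLL-AF9 fusion, an oncogene of acute leukemia, and that the study defines as leukemia-initiating cells. There were 2 wild type and 2 Prl2 knockout libraries. The series asks which genes and pathways differ without PRL2, a small phosphatase, and its title names the p53 pathway. The wild type libraries held 14625725 and 14921313 counts, and the knockout libraries held 15422309 and 15267768, over 13614 genes.

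Ptp4a2, the gene that encodes PRL2, was at 335 ± 12.1 CPM in the wild type and 6.35 ± 0.740 CPM in the Prl2 knockout (SD, n = 2 each). Its counts were 4884 and 5105 in the wild type libraries, and 89 and 104 in the knockout libraries, so each library matched its label. Ptp4a2 fell by 5.72 on the log2 scale (SE 0.144, 95% interval -6.08 to -5.37, edgeR quasi-likelihood test, adjusted p = 0.000586). The knockout libraries kept 1.89% of the wild type level. The gene (ENSMUSG00000028788.14) lies on chromosome 4 from 129811219 to 129850003 in mm10, and the labels do not say which part of it is deleted. The paralogs Ptp4a1 and Ptp4a3, which encode PRL1 and PRL3, had log2 fold changes of 0.91 (SE 0.517, adjusted p = 0.577) and -0.26 (SE 0.116, adjusted p = 0.518) in edgeR's quasi-likelihood test. Over the 3 genes of the family, 1 was called lower over all genes tested and 1 adjusted over the list alone, with a camera adjusted p of 0.0876 for the list. A processed copy on chromosome 2, Gm13422, matches Ptp4a2 at 97.2% identity, so reads between the copies are uncertain. Without Prl2 knockout replicate 1 the adjusted p of Ptp4a2 was 0.104, and without Prl2 knockout replicate 2 it was 0.0829, while the log2 fold changes were -5.61 and -5.84. In these fits the lone knockout library is assumed to vary like the wild type libraries.

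Trp53, the gene of the p53 protein, was at 120 ± 11.7 CPM in the wild type and 128 ± 11.0 CPM in the knockout (SD, n = 2 each), a log2 fold change of 0.09 (SE 0.125, edgeR quasi-likelihood adjusted p = 0.824). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, had a log2 fold change of 0.17 with a 95% interval of -0.37 to 0.72. The interval was -0.33 to 0.38 around 0.02 for Mdm2, the ubiquitin ligase that p53 induces and that degrades p53. Among the pro-apoptotic targets, Bax had -0.01 (SE 0.154), Bbc3, which encodes PUMA, -0.16 (SE 0.216), and Pmaip1, which encodes NOXA, -0.27 (SE 0.364). For Pmaip1 the wild type libraries differed more from each other than the genotypes did, at 198.1 and 97.5 CPM against 127 and 119 in the knockout. Of 37 measured p53 target genes, 18 had a positive and 19 a negative fold change. By edgeR's quasi-likelihood test 0 were called over all genes tested and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05. DESeq2, limma-voom and edgeR's likelihood ratio test also called 0 of them. The mean of the list was 0.09 and its median -0.0018, so the signs differ, with a camera adjusted p of 0.344 (adjusted p = 0.748 with an estimated correlation). The 2 wild type libraries stood on either side of the knockout libraries. Relative to the mean of all libraries, the list was at 0.18 in wild type replicate 1 and -0.27 in wild type replicate 2, against -0.02 and 0.10 in the knockout. Without wild type replicate 1 the mean was 0.30 (camera adjusted p = 0.0118, and adjusted p = 0.869 with an estimated correlation), and without wild type replicate 2 it was -0.14 (camera adjusted p = 0.383). Of 16 regulators of p53, 11 had a positive and 5 a negative fold change, with a list mean of 0.13 (camera adjusted p = 0.269). Trim28, a corepressor that works with MDM2, had a log2 fold change of -0.15 (SE 0.109).

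**Figure D1:**
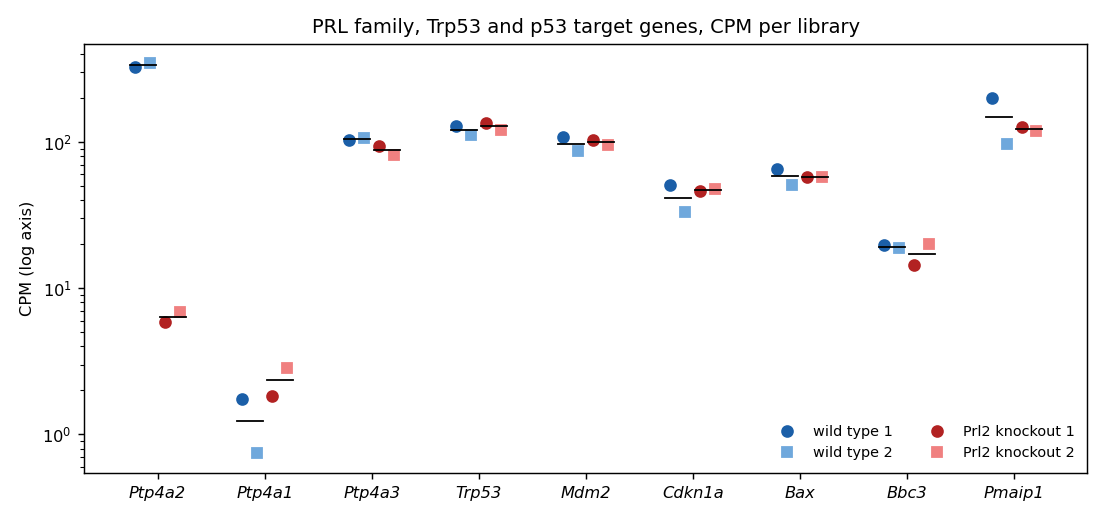
CPM of Ptp4a2, its paralogs, Trp53 and 5 p53 target genes in each library, on a log axis, with wild type libraries in blue, Prl2 knockout libraries in red and black lines for the mean of each genotype. Ptp4a2 lies at 5.82 and 6.87 CPM in the knockout against 327 and 344 in the wild type, while the p53 target genes overlap between the genotypes.

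**Figure D2:**
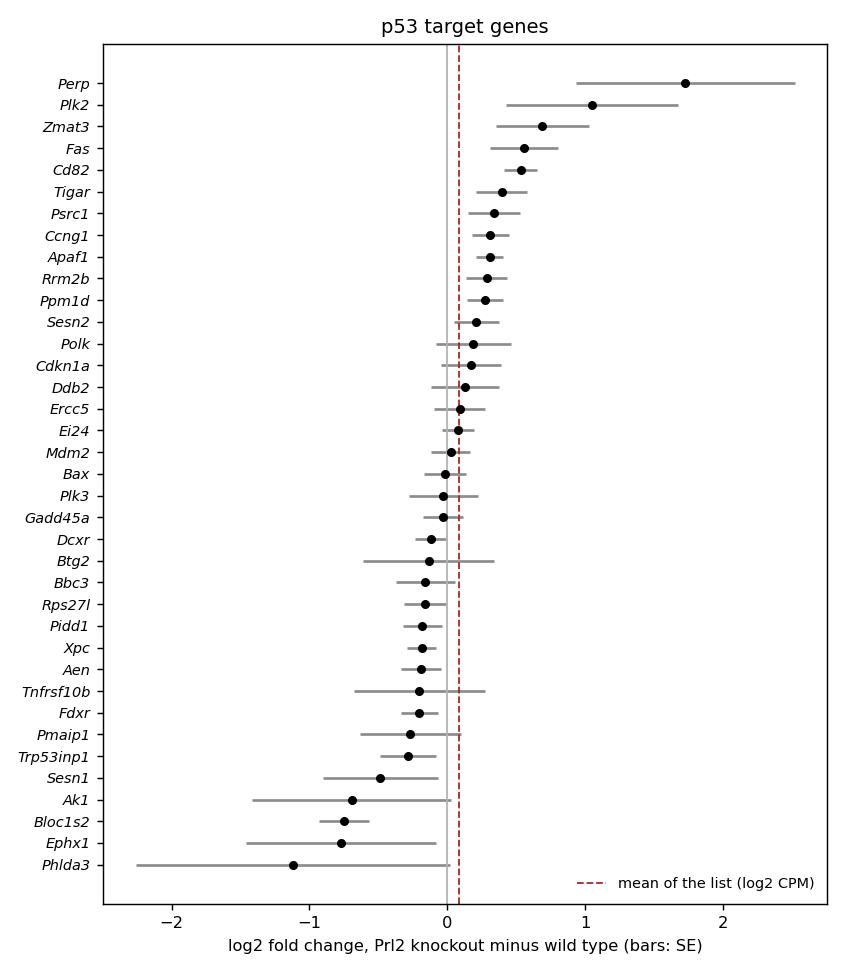
Log2 fold changes of the 37 measured p53 target genes, Prl2 knockout minus wild type, as points with SE bars, and the mean of the list as a dashed line. The genes lie on both sides of 0, with 18 above and 19 below.

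Across the transcriptome, Ptp4a2 was the 1 gene called lower in the knockout and 0 genes were called higher by edgeR's quasi-likelihood test. The next smallest adjusted p was 0.479. At an unadjusted p under 0.05 there were 768 genes with higher and 585 with lower values in the knockout, 1353 together where chance would give 681. limma-voom also called 1 gene lower and 0 higher. DESeq2 called 46 higher and 46 lower, and edgeR's likelihood ratio test called 25 higher and 40 lower. Leaving out wild type replicate 1 gave 6 calls, and leaving out wild type replicate 2 gave 8, while leaving out either knockout library gave 0. In 4 of these 6 and 7 of these 8 genes, a count made after the values were seen, the wild type library left out lay nearer the knockout mean than the other wild type library. Of the 8, Xist, Ddx3y, Kdm5d and Uty are sex-linked and Lin28b is high in wild type replicate 1 alone, so these calls follow that library and not the genotype. Vcam1, the endothelial and macrophage adhesion molecule that binds VLA-4, was called in both of the former, and was chosen after its values were seen. Its counts were 385 and 1635 in the wild type against 6073 and 6881 in the knockout, and its adjusted p over all 4 libraries was 0.497 by the quasi-likelihood test.

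The authors' deposited table lists 65 genes at an adjusted p of 0.05 or less, 25 higher and 40 lower in the knockout, of which 53 are protein-coding and 8 are pseudogenes. Outside Ptp4a2, the genes named from it had a quasi-likelihood adjusted p of 0.479, so they are given as values and not as calls of that test. Slc40a1, the iron exporter ferroportin, was at 40.7 ± 2.65 CPM in the wild type and 114.5 ± 22.1 CPM in the knockout (SD, n = 2 each), with an adjusted p of 1.69e-07 in the authors' deposited table. Paqr5, a membrane progestin receptor, was at 8.62 ± 0.290 and 23.8 ± 0.762 CPM. The log2 fold changes were 2.10 for Mmp25, a membrane-anchored metalloproteinase of leukocytes, and 1.52 for Slc13a5, a citrate transporter. They were 1.10 for the dynein heavy chain Dnah8, 0.98 for Ly75, the endocytic receptor DEC-205, and 0.96 for Mylk, the myosin light chain kinase.

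In the other direction, Ldhb, a subunit of lactate dehydrogenase, was at 22.9 ± 1.69 CPM in the wild type and 5.10 ± 0.731 CPM in the knockout (SD, n = 2 each), with an adjusted p of 4.05e-07 in the authors' deposited table. Cacna1b, the pore subunit of a neuronal calcium channel, had counts of 237 and 274 in the wild type against 4 and 28 in the knockout. Serpine2, a protease inhibitor, had a log2 fold change of -2.54 (SE 0.541), and Apoe, the lipid carrier, -2.05 (SE 0.436). The values were -1.57 (SE 0.250) for Wfdc21, -1.35 (SE 0.210) for Lrg1 and -1.22 (SE 0.276) for Mgst2, a microsomal glutathione transferase. All 65 genes listed in the authors' deposited table had no overlap of the groups' CPM values. Of all genes, 44.2% had none, where chance gives 33.3% for 2 libraries against 2. DESeq2 called 43 of the 65 genes listed in the authors' deposited table.

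**Figure D3:**
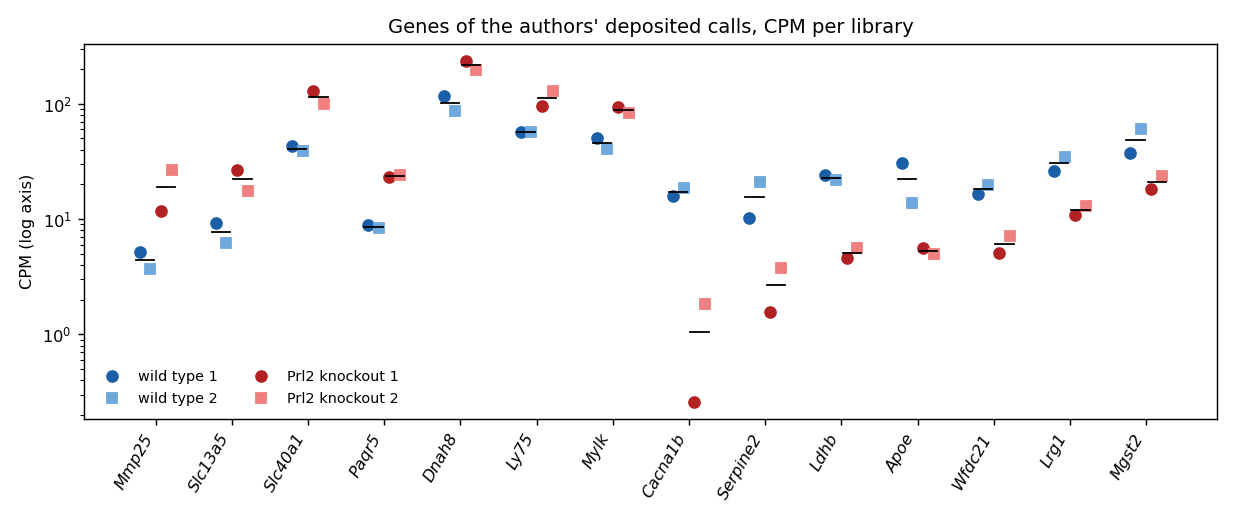
CPM per library, on a log axis, of the genes named from the authors' deposited table besides Ptp4a2, with wild type libraries in blue, Prl2 knockout libraries in red and black lines for the mean of each genotype. Slc40a1 lies at 42.6 and 38.9 CPM in the wild type and at 130.1 and 98.9 in the knockout, and Ldhb at 24.1 and 21.7 against 4.58 and 5.61.

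Cell-cycle genes had higher values in the knockout as lists. All 26 measured genes of the G2/M and mitosis list had a positive fold change, with a mean of 0.35 (camera adjusted p = 2.27e-07, and adjusted p = 0.718 with an estimated correlation). Mki67, the proliferation marker, was at 454 ± 65.4 CPM in the wild type and 662 ± 122.5 CPM in the knockout, and Top2a, the topoisomerase of dividing cells, at 509 ± 26 and 698 ± 99.2 CPM (SD, n = 2 each). Of 26 DNA replication and G1/S genes, 25 had a positive fold change, with a mean of 0.18 (camera adjusted p = 0.00119, and adjusted p = 0.718 with an estimated correlation). Mcm6 and Mcm5, subunits of the replicative helicase, had 0.11 (SE 0.124) and 0.27 (SE 0.139). Of 21 DNA repair genes, 17 had a positive fold change, with a mean of 0.22 (camera adjusted p = 0.00159, and adjusted p = 0.718 with an estimated correlation). The most abundant, the DNA ligase Lig1 and the poly(ADP-ribose) polymerase Parp1, had 0.22 (SE 0.116) and 0.17 (SE 0.122). Over all genes tested 0 members of these 3 lists were called, and 0 adjusted over the list alone, by edgeR's quasi-likelihood test, while 12, 5 and 6 had an unadjusted p under 0.05. DESeq2, limma-voom and the likelihood ratio test also called 0. The G2/M list stayed past the threshold without each library in turn, with a mean of 0.21 without Prl2 knockout replicate 1. The replication list did not without wild type replicate 1 (camera adjusted p = 0.0633). Without Prl2 knockout replicate 1 the replication and repair lists had means of 0.11 and 0.14 (camera adjusted p = 0.135 for both). Genes with a long deposited length also had higher values in the knockout than short ones. Among protein-coding genes with a mean log2 CPM of 3 or more, the median log2 fold change was 0.13 at 7090 bp or more. It was -0.09 at 3007 bp or less.

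Cholesterol synthesis genes had a list mean of 0.33, with 15 of 18 positive (camera adjusted p = 0.00643, and adjusted p = 0.718 with an estimated correlation). Adjusted over the list alone 1 member was called higher, against 0 over all genes tested by the quasi-likelihood test, 3 at an unadjusted p under 0.05, and 1 each by DESeq2 and the likelihood ratio test and 0 by limma-voom. Srebf2, a transcription factor of sterol metabolism, had 0.09 (SE 0.169). Without wild type replicate 1 the mean was 0.18 (camera adjusted p = 0.340), and without Prl2 knockout replicate 1 it was 0.31 (0.0924). Of 29 components of PI3K, AKT, RAS and KIT signalling, 23 had a positive fold change, with a mean of 0.12 (camera adjusted p = 0.0442, and adjusted p = 0.718 with an estimated correlation). This call was lost without any 1 of the 4 libraries, though the mean of the list stayed between 0.10 and 0.13. After removal of each library's trend on gene length its mean was 0.04 (camera adjusted p = 0.468). Akt1 had 0.20 (SE 0.103), and Cbl, a ubiquitin ligase of receptor signalling, 0.15 (SE 0.130).

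Mitochondrially encoded genes had lower values in the knockout. All 10 measured had a negative fold change, with a mean of -0.51 (camera adjusted p = 3.85e-06, and adjusted p = 0.718 with an estimated correlation). Adjusted over the list alone 7 were called lower, against 0 over all genes tested by edgeR's quasi-likelihood test, 7 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom and the likelihood ratio test. mt-Co1, a subunit of cytochrome c oxidase, was at 5351 ± 165 CPM in the wild type and 4240.0 ± 180.5 CPM in the knockout, and mt-Cytb, of complex III, at 2822 ± 95.5 and 1970.0 ± 0.662 CPM (SD, n = 2 each). This list stayed past the threshold without each library in turn. After removal of each library's trend on gene length its mean was -0.38 (camera adjusted p = 0.000232). The nuclear genes of oxidative phosphorylation had a mean of -0.09 (camera adjusted p = 0.194), and Atp5b, a subunit of ATP synthase, had 0.12 (SE 0.108).

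Erythroid markers were low in all libraries and lower in the knockout, with 7 of 7 measured genes negative and a mean of -1.63 (camera adjusted p = 1.65e-05, and adjusted p = 0.718 with an estimated correlation). Hbb-bs, an adult beta-globin gene, had counts of 116 and 62 in the wild type against 16 and 14 in the knockout, and Tfr2, a transferrin receptor, had a log2 fold change of -1.14 (SE 0.492). Adjusted over the list alone 4 members were called lower, against 0 over all genes tested by the quasi-likelihood test, 5 at an unadjusted p under 0.05, 1 each by DESeq2 and the likelihood ratio test and 0 by limma-voom. The call of the list held without each library in turn. All 4 measured B-cell markers were negative, with a mean of -0.77 and a median of -0.36 (camera adjusted p = 0.0442, and adjusted p = 0.718 with an estimated correlation). Vpreb3, chosen after its values were seen, had -3.33 (SE 1.07), from counts of 10 and 12 in the wild type against 0 and 2 in the knockout. Ighm, the heavy chain constant gene of IgM, was at 379.5 ± 11.9 CPM in the wild type and 268 ± 42.7 CPM in the knockout (SD, n = 2 each), and 2 of the 4 were called lower adjusted over the list alone, against 0 over all genes by edgeR's quasi-likelihood test, DESeq2, limma-voom and the likelihood ratio test, with 2 at an unadjusted p under 0.05. The B-cell call was lost without wild type replicate 1 (mean -0.09), wild type replicate 2 (-0.52) or Prl2 knockout replicate 1 (-0.64). After removal of the length trend it was lost too, with a mean of -0.68 (camera adjusted p = 0.0672). The filter was rerun on the libraries left, and without a wild type library it likely dropped Vpreb3. The means of -0.09 and -0.52 therefore cannot be laid to the missing library alone.

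**Figure D4:**
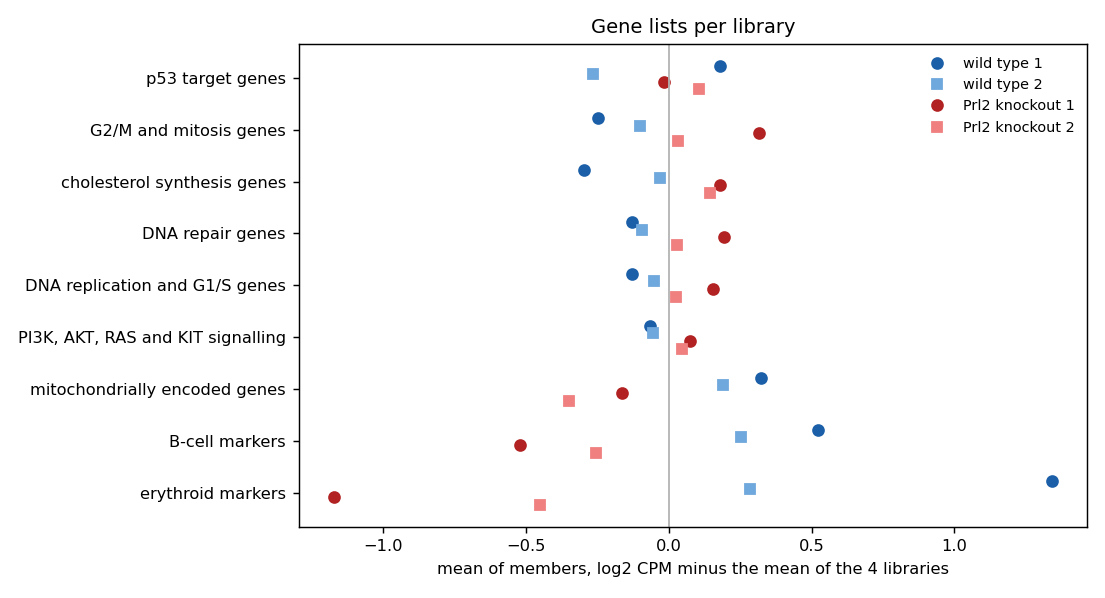
Mean of the members of the p53 target list and of the 8 lists past the camera threshold, in each library, as log2 CPM minus the mean of the 4 libraries, with wild type libraries in blue and Prl2 knockout libraries in red. The p53 target list is at 0.18 and -0.27 in the 2 wild type libraries, on either side of the knockout libraries, and the mitochondrial list at 0.32 and 0.19 in the wild type against -0.16 and -0.35 in the knockout.

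The remaining lists did not pass the camera threshold over the 4 libraries. Of all 37 lists, 14 had a mean that changed sign without at least 1 library, and 32 had one that changed sign or moved by over 1.5 times. The MLL-AF9 and HOXA/MEIS1 programme had 15 of 23 genes negative and a mean of -0.28 (camera adjusted p = 0.236). Its most abundant members, the transcription factor genes Myb and Lmo2, had -0.18 (SE 0.138) and 0.05 (SE 0.105). Hoxa3 was called lower adjusted over the list alone, with counts of 634 and 569 against 327 and 327, and 0 members over all genes by the quasi-likelihood test. DESeq2 and the likelihood ratio test each called 1 member and limma-voom 0, with 2 at an unadjusted p under 0.05. Without wild type replicate 2 the list had a mean of -0.53 (camera adjusted p = 0.0214, and adjusted p = 0.748 with an estimated correlation), and without wild type replicate 1 it had -0.05 (camera adjusted p = 0.965). STAT5 and cytokine response genes had a mean of -0.27 (camera adjusted p = 0.0906), and 0.0463 without wild type replicate 2 and 0.0323 without Prl2 knockout replicate 2 (adjusted p = 0.748 and 0.654 with an estimated correlation), while without wild type replicate 1 the mean was -0.17 (0.498). Interferon response genes had a mean of -0.32 (camera adjusted p = 0.0637), and 0.00400 without wild type replicate 1 and 3.61e-06 without Prl2 knockout replicate 2 (adjusted p = 0.869 and 0.654 with an estimated correlation). Without wild type replicate 2 the interferon mean was -0.16 (0.714) and without Prl2 knockout replicate 1 it was 0.0044 (0.753), as the list was at -0.48 in that library against 0.16 in Prl2 knockout replicate 2. The BCL2 family had 12 of 15 genes negative and a mean of -0.04 (camera adjusted p = 0.344), and Mcl1, an anti-apoptotic member, had -0.18 (SE 0.14). Adjusted over the list alone, Bok was called higher and Bcl2a1a lower, against 0 members over all genes by edgeR's quasi-likelihood test, 2 at an unadjusted p under 0.05, 2 by the likelihood ratio test and 0 by DESeq2 and limma-voom. Bok and Bcl2a1a were chosen after their values were seen. Of the STAT5 list 1 member, Ccnd2, was called lower adjusted over the list alone, against 0 over all genes by the quasi-likelihood test, 3 at an unadjusted p under 0.05, 1 by the likelihood ratio test and 0 by DESeq2 and limma-voom.

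Proliferation and stress lists with camera adjusted p above the threshold included MYC and ribosome biogenesis genes (mean -0.03, adjusted p = 0.767), ERK and immediate-early response genes (0.02, 0.862) and cyclin-dependent kinase inhibitors (-0.09, 0.949). The ATF4 and integrated stress response list had a mean of 0.20 (camera adjusted p = 0.144), and unfolded protein response chaperones -0.10 (0.269). Glycolysis genes had a mean of 0.06 (0.493), antioxidant and NRF2 target genes 0.06 (0.448), FOXO target genes -0.18 (0.661), inflammatory and NF-kB response genes -0.11 (0.767), and homing and adhesion genes 0.04 (0.661). Ncl, the nucleolar protein nucleolin, had a log2 fold change of 0.06 (SE 0.12), and Itgb2, the beta subunit of leukocyte integrins, 0.44 (SE 0.15, edgeR quasi-likelihood adjusted p = 0.493). Of the homing list 1 member, Ccr2, was called lower adjusted over the list alone, against 0 over all genes by the quasi-likelihood test, 3 at an unadjusted p under 0.05, 1 each by DESeq2 and the likelihood ratio test and 0 by limma-voom. Of its 19 measured members 8 had a positive and 11 a negative fold change, with 2.65 (SE 0.791) for Vcam1.

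Among markers of other cell types, neutrophil granule and maturation genes had a mean of -0.13 (camera adjusted p = 0.767, and 0.0118 without wild type replicate 1) and monocyte and macrophage markers -0.14 (0.269, and 0.0335 without Prl2 knockout replicate 2). S100a9, a neutrophil protein, was at 4448 ± 1086 CPM in the wild type and 3864 ± 41.9 CPM in the knockout, and Spi1, which encodes PU.1, at 569 ± 66.3 and 558.5 ± 43.8 CPM (SD, n = 2 each). Adjusted over the list alone 2 monocyte markers, Ccr2 and Csf1r, were called lower, against 0 over all genes by the quasi-likelihood test, 7 at an unadjusted p under 0.05, 3 by DESeq2, 1 by the likelihood ratio test and 0 by limma-voom. Of the 15 measured markers of this list 6 had a positive and 9 a negative fold change. Vcam1, on the same list, had 2.65 (SE 0.791). Stem and progenitor markers had a mean of -0.60 but a median of -0.05 (camera adjusted p = 0.469), and were at 0.80 in wild type replicate 1 against -0.20 in wild type replicate 2. Of its members, Lin28b had -5.93 and Mecom -3.40, both chosen after their values were seen. Eosinophil markers had a mean of 0.73 (camera adjusted p = 0.0637, and 0.000589 without wild type replicate 1), megakaryocyte markers -0.69 (0.0876, and 0.0207 without wild type replicate 2) and mast cell and basophil markers -0.26 (0.448). T-cell and NK-cell markers had -0.91 (0.344, and 0.0490 without wild type replicate 1), dendritic cell and MHC class II markers -0.59 (0.237, and 0.00213 without wild type replicate 2), hepatocyte markers -0.58 (0.269) and stromal and endothelial markers -0.16 (0.344). Other libraries left out moved these means: without wild type replicate 2 the neutrophil mean was 0.19 (camera adjusted p = 0.0910) and the eosinophil mean 0.22 (0.340), and without wild type replicate 1 the dendritic cell mean was 0.21 (0.460) and the megakaryocyte mean -0.37 (0.460). Without Prl2 knockout replicate 1 the monocyte mean was -0.04 and the T-cell mean -0.53 (0.753 for both). None of these calls with 1 library left out held with an estimated correlation. The adjusted p was then 0.869 for the neutrophil, eosinophil and T-cell lists, 0.748 for the megakaryocyte and dendritic cell lists and 0.654 for the monocyte list. With an estimated correlation, none of the 37 lists passed the threshold over the 4 libraries, where the smallest adjusted p was 0.718. This setting raised p even without correlated members. The PI3K list had an estimated correlation of -0.0318, under the preset 0.01, yet its unadjusted camera p went from 0.00955 to 0.0993. Failing it therefore cannot show that a list did not shift. fry called 1 list, the phosphatases of regenerating liver that hold Ptp4a2 (adjusted p = 0.0158), and 4 lists by its mixed p, the p53 target genes among them (adjusted p = 0.0448).

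Wild type replicate 1 stood apart from the other libraries in sex-linked genes. Xist, the RNA of the inactive X chromosome, had 11147 counts there against 9 in wild type replicate 2 and 3 and 12 in the knockout libraries. Ddx3y, a Y-linked gene chosen after its values were seen, had 12 counts there against 1271, 1320 and 1173. The sex-linked list had a camera adjusted p of 0.491, and 0.00213 without wild type replicate 2 (adjusted p = 0.748 with an estimated correlation), and its mean of 1.04 became -0.87 without wild type replicate 1. Wild type replicate 1 thus looks female and the other 3 libraries male, but the labels give no sex. Mid1-ps1, annotated on Y and chosen after its values were seen, went the other way. It had 56 counts in wild type replicate 1 against 21 in wild type replicate 2 and 0 in both knockout libraries. Effects of sex and of this library cannot be told apart in the wild type, which bears on every value that includes it, the p53 target list among them. On that list, however, wild type replicate 2 (-0.27) lay further from the knockout libraries (-0.02 and 0.10) than wild type replicate 1 (0.18) did. The first principal component, with 38.7% of the variance, separated the 2 wild type libraries, and the second, with 36.1%, separated the genotypes. On the first, wild type replicates 1 and 2 lay at -36.7 and 35.5, on either side of the knockout libraries at 15.5 and -14.4.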

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

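The crossed pairing, the removal of the length trend, edgeR's earlier quasi-likelihood method and the fit without X and Y genes were chosen after seeing the data. Calls of genes rested on the tool: 0 higher and 1 lower by edgeR's quasi-likelihood test became 46 and 46 with DESeq2, and 25 and 40 with the likelihood ratio test. On simulated counts, these 2 tools also called 61 and 66 unchanged genes, against 3. The simulated spread was drawn from the quasi-likelihood fit itself, so these counts cannot rank the tools on the real data. With replicate number as a block (replicate block) 0 genes were called higher and 2 lower, and with the crossed pairing 1 and 3. Deviations of same-numbered libraries had a correlation of -0.142. With 2 libraries per genotype the crossed pairing has the opposite sign by construction, so this value cannot tell whether libraries were paired. With the block the lists past the camera threshold lost the PI3K list (adjusted p = 0.0642) and gained the interferon list (0.0210). Without each library in turn, 0 to 4 genes were called higher and 0 to 4 lower, and the log2 fold change of Ptp4a2 lay between -5.84 and -5.61, with its call lost without either knockout library (adjusted p = 0.104 and 0.0829), which leaves 3 libraries. The lone library of a group is then assumed to vary like the other group. The mean of the p53 target genes lay between -0.14 and 0.30 without each library in turn, past the camera threshold without wild type replicate 1 and negative without wild type replicate 2; the cause was not tested. Of the other lists, 8 passed, 0 with an estimated correlation, 3 to 11 without each library in turn and 9 after removal of the length trend, which kept 6, lost the PI3K (0.468) and B-cell (0.0672) lists and gained 3, the MLL-AF9 (0.0495), phosphatase (0.0495) and eosinophil (0.0324) lists. Other scaling factors, the fit without robust estimation, a CPM minimum of 1 and the 2-fold minimum left both counts of calls as they were. The fit with no filter tested the same genes, since the table was filtered before deposit. Over 60 other named genes and 779 values under alternatives, 719 kept their side of the threshold and direction. A further 35 were newly called, 17 of them by DESeq2 and 16 by the likelihood ratio test. Another 25 changed sign with no call either way and 0 reversed with a call. None of these genes was called in the main fit, so keeping a side meant staying uncalled and no call could be lost.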

Other observations

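The tests of retrocopy parents near Ptp4a2, of single library pairs for the length trend and of single libraries for the G2/M list were chosen only after related values had been seen, as were the genes named here outside the fixed lists. All 67 protein-coding genes of the cytosolic ribosomal proteins with a mean log2 CPM of 3 or more had a negative log2 fold change. Their median was -0.33. They lay at 0.22 and 0.11 in the wild type libraries against -0.20 and -0.14 in the knockout libraries. Bok, a BCL2 family gene, had counts of 9 and 1 in the wild type against 36 and 52 in the knockout, and Bcl2a1a had 17 and 17 against 2 and 3. Bcl11a, a repressor of fetal globin genes, had 40 and 27 counts against 2 and 4, and Ccnd2, which encodes cyclin D2, 74 and 90 against 26 and 26. Ccr2, a chemokine receptor of monocytes, had 553 and 584 against 278 and 320, and Csf1r, the M-CSF receptor, 1491 and 1613 against 1180 and 1065. Each of these genes had an adjusted p of 0.479 by edgeR's quasi-likelihood test.

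Single libraries also stood apart. Lin28b, an RNA-binding protein of fetal stem cells, had 2169 counts in wild type replicate 1 against 7 in wild type replicate 2 and 24 and 12 in the knockout libraries. The Y-linked gene Eif2s3y had 1112 counts in wild type replicate 2 and 1034 in Prl2 knockout replicate 1, and 3 in Prl2 knockout replicate 2, where the Y-linked genes Kdm5d and Uty had 565 and 327. Mid1-ps1, a pseudogene annotated on Y, differed between the genotypes instead. It had 56 and 21 counts in wild type replicates 1 and 2 and 0 in both knockout libraries, at least 13.1-fold lower against 3 counts per library. Its adjusted p was 4.54e-06 in the authors' deposited table and 0.479 by edgeR's quasi-likelihood test. Its highest count lay in wild type replicate 1, where Kdm5d and Uty had 0 and 1 counts, so it did not follow these Y-linked genes.

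Retrocopies among the genes of the authors' deposited table had parents near Ptp4a2. Gm13422, a copy of Ptp4a2, had 81 and 50 counts in the wild type and 0 in both knockout libraries, while the Hdac1 copies AC125456.1 (2 and 7 against 73 and 122) and Gm4864 (18 and 26 against 88 and 144) and the Rbbp4 copy Gm48609 (3 and 6 against 54 and 87) went the other way. Reads of these parents, which lie 0.295 and 0.504 Mb from Ptp4a2, may have been assigned to the copies in the knockout, but this stays open: 4 of 6 listed retrocopies had a parent within 1 Mb against 4 of 1080 others (Fisher's exact test, two-sided, p = 1.81e-08), a count made once those parents had been seen, so it describes the pattern and does not test it, and the parents differ, with log2 fold changes of -0.90 (SE 0.294) for Hdac1 and 0.30 (SE 0.0997) for Rbbp4, as do the 4 unlisted copies, with 1.06 for Gm7200 and 0.40 for Gm4800 (Rbbp4), 1.10 for Gm8539 (Zbtb8os) and -0.08 for Gm10093 (Hdac1, 99.4% identity). A wider segment that differs in sequence between the genotypes stays open too. The 11 unlisted retrocopies with parents within 5 Mb, the 4 unlisted copies just named among them, had a mean absolute statistic of 1.06. Retrocopies of other parents had 0.987 (one-sided permutation p = 0.362). A p of 0.05 or more was set in advance to count against such a segment, yet the difference of 0.0715 has an SE of 0.256. Such a segment would travel with the genotype labels, so its effects and those of PRL2 loss on these genes cannot be told apart here, and the 30 protein-coding genes within 1 Mb had a mean absolute statistic of 1.47 against 1.21 elsewhere (one-sided permutation p = 0.0833).

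Over 9096 protein-coding genes with a mean log2 CPM of 3 or more, log2 fold change increased with the deposited gene length. That length is not the genomic span. Spearman's rho was 0.341 across genes, which are not independent replicates. Without ribosomal protein, mitochondrial and cell-cycle genes rho was 0.322, and with GC content held fixed by ranks it was 0.326, so neither accounts for the trend. The 4 pairs of a knockout and a wild type library had rho between 0.228 and 0.334, against 0.0101 between the wild type libraries and -0.113 between the knockout libraries, which argues against a single library as the source. Differences in RNA quality or in library preparation between the genotypes were not tested and stay open, as does the genotype itself.

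The higher G2/M and mitosis genes may be part of this length trend, but after each library's trend was removed their mean was 0.32, against 0.35 before (camera adjusted p = 1.75e-07 after removal). Without 1 library in turn the smallest mean was 0.206, without Prl2 knockout replicate 1, so 1 library alone does not account for all of it. Relative to the mean of all libraries, the list was at -0.25 and -0.10 in the wild type libraries. It was at 0.32 and 0.03 in Prl2 knockout replicates 1 and 2, so much of the shift lay in replicate 1. The members moved together, with an estimated correlation of 0.821, and with that correlation the list did not pass the threshold (adjusted p = 0.718). That failure cannot be laid to the correlation alone, as the PI3K list, with an estimated correlation of -0.0318, failed with its own estimate too. A difference in the share of dividing cells at collection, from culture or from genotype, stays open as a hypothesis.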
